A study of Mus musculus with 16 samples.

How the data were processed

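RNA of tumor and peri-tumor liver of 8 mice was sequenced, 16 libraries in all, with total RNA isolated by the mirVana method and libraries made with the VAHTS stranded mRNA-seq kit, per the labels' protocols. The protocols name Ras-transgenic and DEN-induced mice together, and whether DEN was given to these mice is not stated. The composition and dose of the decoction are not given in the sources used here. The deposited table of counts holds whole numbers of reads per gene for each library, made by the authors before deposit without scaling, per the file headers and the values themselves. The deposited FPKM files hold the authors' FPKM values per library, counts divided by gene length and by the library's total. The FPKM values were checked against the counts and gave the same lengths in all libraries, with a highest deviation of 0.0592% over 14902 genes and 0 values that were 0 in only 1 of the files, so they were not tested again. The submitters' processing notes name the builds mm9 and mm10, and the aligner and the counting tool are not given in the sources used here.

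The table holds 54838 genes, of which 115 have no symbol (at most 0.0171% of a library) and 27552 had 0 counts in every library. No library was left out, and no library was a copy of another, with a chi-square per degree of freedom of at least 16.87 between libraries of a group. Totals of 13947483 to 16194224 counts per library set the depth. The counting intervals and the floors of 3 counts over a group cover counting error only, not the spread between mice. Animal codes in the labels pair the 2 tissues of each mouse. Once the group means were removed, tumor and peri-tumor libraries of the same mouse correlated at 0.15, 0.12, 0.063 and 0.23 in control and 0.24, 0.043, 0.091 and 0.11 in TCM mice, and 7 of 8 mice correlated best with themselves. Libraries of different treatments share only a number, and they were not paired.

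Counts were scaled and tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr filter (count minimum 10) on the 4 groups and 1 fit of all 16 libraries with a mean per group and 12 residual degrees of freedom. Quasi-likelihood F tests were run on 14865 genes for tumor against peri-tumor tissue within each treatment, for TCM against control within each tissue, and for the difference of the tumor effect between treatments. Genes with p under 0.05 after Benjamini-Hochberg adjustment per comparison were called. Test, filter, comparisons, gene lists and alternatives, except leaving out control mouse 4, were set before the data were seen. CPM values are counts over the TMM-scaled total, group values are means with the SD of 4 libraries, and standard errors (SE) are the log2 fold change over the square root of its F value.

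Of 52 gene lists fixed in advance, the 49 with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Each was also tested with the correlation estimated per list, and the edgeR p values of its members were adjusted over the list alone. Genes were named by a rule set in advance. In the 4 pairwise comparisons it took the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 CPM in the higher group, no overlap between the 4 and 4 libraries and a gene name other than a number of a predicted or cloned transcript. For the difference of the tumor effect it took the 10 lowest p, and for each list up to 4 members with the lowest p and a mean of at least 1 CPM. Hras, Nras, Afp, Gpc3, Igf2, H19, Dusp6, Mki67, Alb, Cyp7a1, Glul, Cyp2b10, Cyp3a11, Cyp1a2, Xist and Ddx3y were followed throughout, and genes outside the rule were added where the text compares comparisons. Some genes that the rule names are not reported here. Shared sequence is the percent of a gene's 50-base words, over its longest transcript in GENCODE M21, that also occur in other genes.

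The alternatives were RLE factors, DESeq2 1.42.0, limma-voom with sample weights, no filter, a filter of 1 CPM in 4 libraries, only the groups compared, the mouse or the replicate number as a block, fry in place of camera, and each library left out in turn. The test was tried on simulated data with known 2-fold and 4-fold changes. It found 55.6% and 91% of them for tumor against peri-tumor in control mice (7.26% of calls false, 14653 genes), 54.5% and 86.7% in TCM mice (2.45%, 14645 genes), 51% and 91.8% for treatment in peri-tumor tissue (7.95%, 14631 genes), 65.3% and 86.6% in tumors (5.52%, 14620 genes) and 26% and 67.7% for the difference of the tumor effect (7.96%, 14645 genes).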

Results

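The data set holds 16 RNA-seq libraries of mouse liver, all from mice that the labels give as HrasG12V, a form of the Ras oncogene that drives liver tumors. Tumor tissue and the liver tissue around it (peri-tumor) were taken from 4 control mice and from 4 mice given a traditional Chinese medicine (TCM) decoction. Each of the 4 groups thus holds 4 libraries, and each mouse gives 1 library of each tissue. The labels add 3 months without saying whether this is the age or the length of treatment, and the series text gives the question as how the decoction acts against liver tumors. Total counts per library ran from 13947483 to 16194224. Transcripts counted for the mouse gene Hras had 38.2 ± 3.73 CPM (counts scaled for library size, mean ± SD, n = 4) in control peri-tumor, 39.6 ± 5.9 in control tumor, 29.8 ± 2.32 in TCM peri-tumor and 36.5 ± 5.6 in TCM tumor tissue. They were called in none of the 5 comparisons (adjusted p 0.0735 to 0.777, edgeR quasi-likelihood test, Benjamini-Hochberg), and whether the counts include transgene reads is not given in the sources used here. Every library had 0 to 2 counts of Xist and 587 to 1242 of Ddx3y.

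In a principal component analysis of all tested genes, component 1 held 54.6% of the variance and parted tumor from peri-tumor tissue, with group means of -59.18 (control peri-tumor), -65.37 (TCM peri-tumor), 77.16 (control tumor) and 47.39 (TCM tumor). Component 2 held 12.7% and parted treatments, except that both libraries of control mouse 4 lay apart from the other controls. On it the peri-tumor library of that mouse stood at 3.848, against -56.96 to -38.64 for the other 3, and its tumor library at -4.492, against -28.73 to -19.18, while TCM libraries lay between 21.54 and 38.21.

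**Figure D1:**
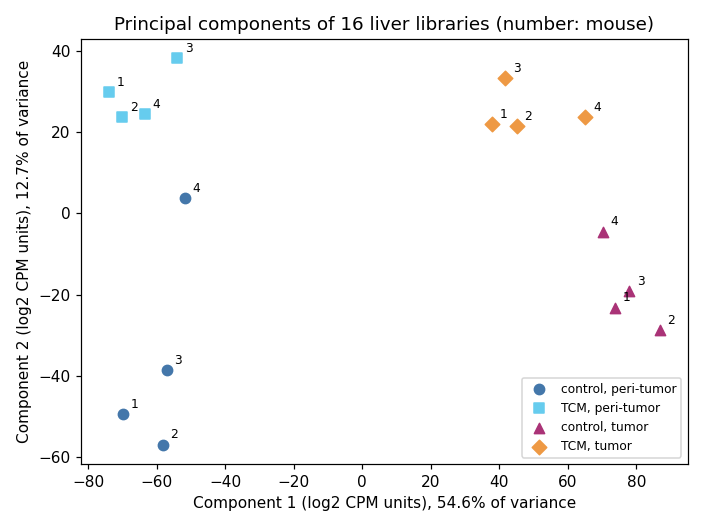
Principal components of log2 CPM for the 16 libraries, with component 1 (54.6% of the variance) on the horizontal axis and component 2 (12.7%) on the vertical axis, colored by group and numbered by mouse. Tumor libraries lie at the right, TCM libraries at the top, and control mouse 4 lies between the other controls and the TCM libraries.

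In control mice, tumors had far higher levels of the fetal liver genes Afp and Gpc3 and lower levels of Glul, Cyp1a2, Cyp7a1 and Cyp3a11, made by mature hepatocytes. The tumor marker Gpc3 rose from 3.42 ± 1.97 CPM in peri-tumor tissue to 532 ± 233 in tumors (155-fold, log2 7.28 ± 0.84 SE), and alpha-fetoprotein (Afp) from 4.93 ± 2.79 to 562 ± 308 (114-fold, log2 6.83 ± 0.70). Glutamine synthetase (Glul), made by hepatocytes around the central vein, fell by 3.54 ± 0.36 on the log2 scale, and Cyp1a2, Cyp7a1 and Cyp3a11 had log2 fold changes of -3.87, -4.88 and -2.34. The proliferation gene Mki67 rose from 3.35 ± 0.655 to 13.7 ± 1.51 CPM (log2 2.03 ± 0.41). Adjusted p for these 7 genes ran from 1.99e-06 to 8.79e-04 (edgeR quasi-likelihood test, Benjamini-Hochberg). Of 14865 tested genes, 6415 changed (43.2%), 3271 up and 3144 down, and 3001 of them by at least 2-fold. Without control tumor 1 the fold moved over 1.5 times for Cyp7a1 (-5.495).

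Among the genes with the largest rises in control tumors, Arhgap40 had 0 counts in all 4 peri-tumor libraries and was at least 134-fold higher in tumors, against a floor of 3 counts over the group. Pla2g2e and Tmem150c, each with 1 count over the peri-tumor libraries, were 476-fold (95% interval 85.1 to 18800) and 419-fold higher (74.9 to 16600), and without the library with that count, control peri-tumor 3 and 2, at least 119-fold and 103-fold. The chemokine Cxcl17, the cadherins Cdhr2 and Cdh17, the transcription factor Tcf24, the calcium channel Cacna1b, the protease inhibitor Spink1 and the sulfotransferase Sult2a2 rose with log2 fold changes of 7.95, 7.94, 7.91, 7.92, 7.70, 7.61 and 7.498. The largest falls were in Hamp2 (-7.22), Orm3 (-6.499), Lrtm1 (-6.21), Hectd2os (-5.81), Cyp2c37 (-5.70), Sult5a1 (-5.501), Cyp2c54 (-5.42), Mup11 (-5.33), Cyp2c69 (-5.26) and Nnmt (-5.14). Adjusted p of these genes ran from 3.12e-08 to 0.00283 (edgeR quasi-likelihood test, Benjamini-Hochberg), and in each the 4 tumor libraries lay on 1 side of the 4 peri-tumor libraries. The folds of Mup11, Cyp2c69, Sult2a2 and Igf2 are uncertain, since 89%, 54.8%, 62.1% and 75.9% of their 50-base words also occur in other genes. Of the genes followed in every comparison, H19 (3.87), Igf2 (5.33), Dusp6 (0.68), Ddx3y (0.46) and Alb (0.60) also rose, while Nras (0.09) and Cyp2b10 (-2.09, adjusted p = 0.0524, edgeR quasi-likelihood test, Benjamini-Hochberg) were not called. Without control peri-tumor 3 the fold moved over 1.5 times for Cxcl17 (8.74), Cdh17 (8.64) and Tcf24 (8.60), without control peri-tumor 4 for Cacna1b (8.53), Spink1 (8.21) and Igf2 (6.17), without control peri-tumor 1 for Sult2a2 (8.79), without control tumor 2 for Sult2a2 (6.81), H19 (3.03) and Igf2 (4.15). Without control peri-tumor 2 the fold moved over 1.5 times for Hamp2 (-6.08) and Cyp2c69 (-4.59), without control tumor 4 for Hectd2os (-6.75), Sult5a1 (-7.98), Mup11 (-8.07) and Nnmt (-6.05). Igf2 without control tumor 2 (adjusted p 0.059), Ddx3y without control tumor 1 (adjusted p 0.0508) and Alb without any 1 library but control peri-tumor 4 and control tumor 4 (adjusted p 0.067 to 0.145) were no longer called (edgeR).

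Limma camera (Benjamini-Hochberg) called 28 of 49 gene lists in control tumors, 13 up and 15 down, with a preset correlation of 0.01. With the correlation estimated per list 0 of these 28 stayed called. Counts over the list alone are in parentheses, and the rest was not called. Log2 fold changes follow each example gene, adjusted p values follow the order of the lists, a list mean stands apart by Dixon's test, and a gene marked uncertain has at least 25% of its 50-base words in other genes. Of 22 RAS to ERK output genes, 18 rose and 0 fell (19 and 1), with Dusp5 at 4.05, Spry2 at 3.54 and Etv4 at 3.86. Of 50 cell cycle genes, 36 rose and 1 fell (37 and 1), with Ccnb1 (uncertain) at 2.83 and Ect2 at 1.96. Of 33 oncofetal and liver tumor markers, 27 rose and 2 fell (28 and 2), with Anxa2 at 4.05, Scd2 at 4.69 and Prom1 at 5.62. Of 22 YAP target genes, 11 rose and 1 fell (15 and 3), with Igfbp3 at 4.86 and Nt5e at 2.62. Of 17 Notch and progenitor genes, 13 rose and 2 fell (13 and 2), with Tnfrsf12a at 3.20 and Spp1 at 5.58. Of 24 p53 target genes, 17 rose and 3 fell (17 and 4), with Cdkn1a at 4.06 and Tnfrsf10b at 5.12, and control peri-tumor 3 apart in the list mean. Of 28 NRF2 target genes, 16 rose and 3 fell (16 and 4), with Gsta1 (uncertain) at 5.30 and Srxn1 at 2.38. For signaling, growth and tumor markers, camera gave adjusted p = 0.0613, 0.308, 0.0613, 0.111, 0.0613, 0.284 and 0.457 with an estimated correlation. Of 15 Ras family genes, 5 rose and 1 fell (5 and 1), with Rras at 0.56 and Nf1 at 0.64, a list that was not called (adjusted p = 0.284, limma camera). Of 32 unfolded protein and integrated stress genes, 13 rose and 1 fell (14 and 1), with Phgdh (uncertain) at 4.29 and Shmt2 at -1.02. Of 21 immediate early genes, 12 rose and 1 fell (13 and 1), with Klf6 at 2.02 and Btg2 at 2.57. Of 39 extracellular matrix genes, 30 rose and 1 fell (32 and 1), with Lamc1 at 1.81 and Fbn1 at 2.58. Of 25 cholesterol synthesis genes, 20 rose and 1 fell (20 and 1), with Lss at 2.29 and Mvd at 2.10. Of 19 recruited macrophage markers, 14 rose and 1 fell (14 and 1), with Cd9 at 2.23 and Ms4a7 at 2.86, and control tumor 4 apart in the list mean. Of 13 cholangiocyte markers, 5 rose and 1 fell (5 and 1), with Bicc1 at 3.55 and Krt23 at 3.04. From stress genes to cholangiocyte markers, camera gave adjusted p = 0.365, 0.152, 0.284, 0.301, 0.334 and 0.152 with an estimated correlation.

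Most lists of hepatocyte function were called down in control tumors, again with counts adjusted over the list alone in parentheses, but not hepatocyte secreted proteins (8 rose and 12 fell, limma camera adjusted p 0.146) or gluconeogenesis genes (2 and 7, 0.296). Of 29 pericentral hepatocyte genes, 2 rose and 26 fell (2 and 26), with Cyp27a1 at -2.58, Gulo at -1.63 and Notum at -3.56. Of 30 periportal hepatocyte genes, 3 rose and 20 fell (3 and 20), with Ass1 (uncertain) at -2.25 and Hpd at -4.16. Of 52 urea cycle and amino acid breakdown genes, 1 rose and 47 fell (1 and 47), with Haao at -2.09, Dmgdh at -2.62 and Hgd at -2.004. Of 31 bile acid genes, 3 rose and 23 fell (3 and 23), with Baat at -1.71 and Slc27a5 at -1.76. Of 18 Wnt targets and regulators, 4 rose and 12 fell (4 and 13), with Tbx3 at -2.71 and Ccnd1 at 1.86, and control peri-tumor 1 apart in the list mean. Across zonation, nitrogen and bile acid lists, camera gave adjusted p = 0.152, 0.0613, 0.0613, 0.0613 and 0.236 with an estimated correlation. Of 45 fatty acid oxidation genes, 7 rose and 23 fell (7 and 24), with Acadvl at -0.75 and Fgf21 at 4.86, and control peri-tumor 4 apart in the list mean. Of 54 nuclear-encoded oxidative phosphorylation genes, 0 rose and 52 fell (0 and 53), with Sdhb at -1.06 and Uqcrb at -0.96. Of 13 mitochondrially encoded genes, 0 rose and 11 fell (0 and 11), with mt-Cytb at -1.13 and mt-Nd2 at -0.98. Of 45 cytochrome P450 and phase I genes, 3 rose and 33 fell (3 and 34), with Cyp2j5 at -2.94 and Cyp3a25 (uncertain) at -2.34. Of 42 phase II conjugation genes, 6 rose and 23 fell (7 and 23), with Ugt3a1 at -3.53 and Gstk1 at -1.89. Of 27 male-biased liver genes, 0 rose and 18 fell (0 and 19), with Ugt2b1 at -2.37. For energy and xenobiotic lists, camera gave adjusted p = 0.339, 0.128, 0.365, 0.128, 0.308 and 0.401 with an estimated correlation. Of 32 acute phase proteins, 3 rose and 14 fell (3 and 14), with Crp at -2.09 and Saa4 at -1.43. Of 34 complement and coagulation genes, 5 rose and 24 fell (5 and 25), with Mbl1 at -2.20 and F7 at -1.43. Of 17 Kupffer cell markers, 0 rose and 15 fell (0 and 16), with Fcna at -3.44, Clec4f at -3.17 and Cd163 at -3.62. Of 9 erythroid markers, 0 rose and 4 fell (0 and 6), with Alas2 at -1.95. For plasma protein and blood cell lists, camera gave adjusted p = 0.334, 0.111, 0.284 and 0.334 with an estimated correlation. The list of acute phase proteins without control peri-tumor 4 (adjusted p 0.0618) and the list of erythroid markers without control peri-tumor 3 or 4 or control tumor 3 or 4 (adjusted p 0.0528 to 0.13), with the filter of 1 CPM in 4 libraries (0.0507) and with only the groups compared (0.0503) lost their camera call. In IGF axis genes (-0.37, 0.46 and down), not called, the median, mean and camera direction differed in sign.

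In TCM mice, tumors differed from peri-tumor tissue in the same markers. Gpc3 rose from 1.99 ± 1.94 to 292 ± 228 CPM (149-fold, log2 7.22 ± 0.85) and Afp from 7.08 ± 7.71 to 309 ± 27.9 (44-fold, log2 5.46 ± 0.66). Mki67 rose from 3.63 ± 3.13 to 30.3 ± 10.9 CPM (log2 3.08 ± 0.42), and H19 rose too (4.45). Glul (-2.17), Cyp1a2 (-2.68), Cyp7a1 (-2.20) and Cyp3a11 (-2.06) fell, with adjusted p for these 8 genes of 1.65e-05 to 0.0133 (edgeR quasi-likelihood test, Benjamini-Hochberg). Nras (0.19), Dusp6 (0.21), Alb (0.28), Igf2 (0.76) and Ddx3y (-0.07) were not called. In all, 4897 genes changed (32.9%), 2572 up and 2325 down, 2290 of them by at least 2-fold. Without TCM peri-tumor 3 the fold moved over 1.5 times for Gpc3 (8.04), Afp (6.57), Mki67 (3.83) and H19 (5.96).

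The sulfotransferase Sult2a2 had 0 counts in all 4 TCM peri-tumor libraries and was at least 141-fold higher in tumors. With 1 to 3 counts over the peri-tumor group, Csn3 was 316-fold (87.3 to 2620) higher, Tmc5 256-fold (87.3 to 1240), Pcdhgc4 329-fold (58.7 to 13100), the cell cycle inhibitor Cdkn2a 167-fold (56.8 to 812) and Cxcl17 163-fold (55.5 to 794), with 95% counting intervals. The bound of Sult2a2 was 79.4-fold without TCM tumor 3, Tmc5 was 105.97-fold higher without TCM tumor 4, Cxcl17 379-fold without TCM peri-tumor 3, Csn3 at least 158-fold without TCM peri-tumor 2, and Pcdhgc4, Tmc5 and Cdkn2a at least 80.6-fold, 188-fold and 123-fold without TCM peri-tumor 4. Sult2a2 and Pcdhgc4 are uncertain, with 62.1% and 41.6% of their words shared. Cdh17 (7.78), the hexokinase Hkdc1 (7.16) and Spink1 (6.998) were the other large rises on the log2 scale. Moxd1 (-4.30), the protease Capn8 (-4.12), Lrtm1 (-4.03), Nnmt (-4.02), Sult5a1 (-3.87), Cyp2b10 (-3.86) and Olig1 (-3.85) fell most, along with the major urinary proteins Mup1 (-4.06), Mup15 (-3.97) and Mup12 (-3.93), whose values are uncertain since 94.8%, 100% and 85.4% of their 50-base words occur in other genes. Adjusted p of these 20 genes ran from 2.48e-07 to 0.0445 with Gpc3 included (edgeR quasi-likelihood test, Benjamini-Hochberg). Without TCM peri-tumor 3 the fold moved over 1.5 times for Cdh17 (9.51), Hkdc1 (10.40) and Spink1 (9.43), without TCM tumor 4 for Cdh17 (6.77) and Hkdc1 (6.43), without TCM tumor 1 for Moxd1 (-5.64), Nnmt (-4.75), Cyp2b10 (-4.53), Mup1 (-5.14), Mup15 (-5.40) and Mup12 (-5.22). Moxd1 without any 1 library but TCM tumor 1 (adjusted p 0.0574 to 0.106), Mup15 without TCM peri-tumor 1 or 3 or TCM tumor 2, 3 or 4 (adjusted p 0.0547 to 0.082) and Mup12 without TCM peri-tumor 1 or 3 or TCM tumor 2, 3 or 4 (adjusted p 0.0516 to 0.0834) were no longer called (edgeR).

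Limma camera (Benjamini-Hochberg) called 29 of 49 gene lists in TCM tumors, 16 up and 13 down, with a preset correlation of 0.01. With the correlation estimated per list 0 of these 29 stayed called, and fry did not call T and NK cell markers (adjusted p 0.126). Counts over the list alone are in parentheses, and the rest was not called. Of 22 RAS to ERK output genes, 14 rose and 0 fell (16 and 1), with Spry2 at 2.97 and Dusp5 at 2.76. Of 50 cell cycle genes, 38 rose and 0 fell (42 and 1), with Rrm2 at 1.95 and Birc5 at 3.17. Of 33 oncofetal and liver tumor markers, 23 rose and 2 fell (26 and 2), with Anxa2 at 3.58 and Scd2 at 3.70. Of 22 YAP target genes, 10 rose and 0 fell (10 and 0), with Ajuba at 1.93 and Nt5e at 1.87, and TCM tumor 1 apart in the list mean. Of 17 Notch and progenitor genes, 9 rose and 1 fell (12 and 1), with Tnfrsf12a at 3.12 and Hes1 at 1.28. Of 24 p53 target genes, 9 rose and 1 fell (10 and 1), with Tnfrsf10b at 3.69 and Cdkn1a at 2.18. Of 32 unfolded protein and integrated stress genes, 9 rose and 2 fell (9 and 2), with Psat1 at 3.92 and Nupr1 at 2.39. Of 21 immediate early genes, 7 rose and 0 fell (7 and 0), with Klf6 at 1.40 and Ier5 at 1.38. Of 25 cholesterol synthesis genes, 17 rose and 0 fell (20 and 0), with Lss at 2.70 and Mvd at 2.05. For growth, marker and signaling lists, camera gave adjusted p = 0.109, 0.143, 0.0825, 0.109, 0.0825, 0.445, 0.445, 0.342 and 0.324 with an estimated correlation. The list of unfolded protein and integrated stress genes without TCM peri-tumor 1 or TCM tumor 3 (adjusted p 0.0529 to 0.0798) and the list of immediate early genes without TCM peri-tumor 2 or TCM tumor 1 (adjusted p 0.0577 to 0.0701) lost their camera call. Of 39 extracellular matrix genes, 26 rose and 2 fell (27 and 2), with Col4a1 at 2.55 and Lamc1 at 1.31. Of 23 antigen presentation genes, 11 rose and 0 fell (15 and 0), with Tap1 at 0.98 and H2-Q4 at 0.89. Of 26 cytokine and chemokine genes, 13 rose and 4 fell (15 and 4), with Icam1 at 1.64 and Cxcl12 at -1.45. Of 19 recruited macrophage markers, 10 rose and 1 fell (11 and 1), with Cd9 at 1.96 and Ms4a7 at 2.43. Of 21 T and NK cell markers, 3 rose and 0 fell (0 and 0), with Lck at 1.40 and Trbc2 (uncertain) at 1.42, neither called. Of 13 cholangiocyte markers, 5 rose and 0 fell (5 and 0), with Bicc1 at 2.94 and Sox9 at 1.04. Of 22 female-biased liver genes, 12 rose and 2 fell (13 and 2), with Abcd2 at 3.67 and Trim24 at 1.36. For matrix, immune and sex-biased lists, camera gave adjusted p = 0.343, 0.445, 0.445, 0.373, 0.636, 0.172 and 0.432 with an estimated correlation. The list of cytokine and chemokine genes without TCM tumor 1 (adjusted p 0.075), with the filter of 1 CPM in 4 libraries (0.0755) and with only the groups compared (0.0753) and the list of T and NK cell markers without TCM tumor 1 or 2 (adjusted p 0.0884 to 0.263), with the filter of 1 CPM in 4 libraries (0.0837) and with only the groups compared (0.136) lost their camera call. The median of the female-biased list was log2 1.56, or 1.44 with 2 members that had 0 counts in a group set at their bound.

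Hepatocyte lists were called down in TCM tumors as well, with counts adjusted over the list alone in parentheses, but not hepatocyte secreted proteins (10 rose and 6 fell, limma camera adjusted p 0.421) or gluconeogenesis genes (2 and 4, 0.201). Of 29 pericentral hepatocyte genes, 1 rose and 24 fell (1 and 25), with Cyp27a1 at -1.75 and Aldh1a1 at -1.76. Of 30 periportal hepatocyte genes, 4 rose and 19 fell (4 and 19), with Hal at -1.42 and Ass1 (uncertain) at -1.28. Of 52 urea cycle and amino acid breakdown genes, 1 rose and 41 fell (1 and 43), with Slc25a15 at -1.09 and Hgd at -1.32. Of 31 bile acid genes, 0 rose and 22 fell (0 and 22), with Hsd17b4 at -0.85 and Slc10a1 at -2.11, and TCM peri-tumor 3 apart in the list mean. Of 18 Wnt targets and regulators, 4 rose and 9 fell (4 and 10), with Rspo3 at -1.96 and Tcf7 at 1.15. For zonation, nitrogen, bile acid and Wnt lists, camera gave adjusted p = 0.185, 0.0937, 0.0825, 0.0825 and 0.373 with an estimated correlation. The list of Wnt targets and regulators without TCM peri-tumor 4 (adjusted p 0.065), with only the groups compared (0.0565) lost its camera call. Of 45 fatty acid oxidation genes, 3 rose and 29 fell (3 and 30), with Cpt2 at -0.96 and Eci2 at -0.97. Of 54 nuclear-encoded oxidative phosphorylation genes, 1 rose and 42 fell (1 and 45), with Cox7a2 at -0.87 and Ndufs1 at -0.66. Of 13 mitochondrially encoded genes, 0 rose and 12 fell (0 and 13), with mt-Nd5 at -1.04 and mt-Co1 (uncertain) at -1.09. Of 45 cytochrome P450 and phase I genes, 4 rose and 27 fell (5 and 28), with Ces2a at -1.86 and Cyp2c38 at -2.40. Of 42 phase II conjugation genes, 2 rose and 27 fell (2 and 27), with Mgst1 at -1.71 and Gstk1 at -1.45. Of 27 male-biased liver genes, 0 rose and 19 fell (0 and 22), with Ugt2b1 at -2.44 and Susd4 at -3.34. Of 34 complement and coagulation genes, 5 rose and 14 fell (5 and 16), with Mbl1 at -1.28 and C8b at -2.14. Of 17 Kupffer cell markers, 0 rose and 7 fell (0 and 8), with Fcna at -1.66 and Clec4f at -1.61. From fatty acid oxidation to Kupffer cells, camera gave adjusted p = 0.109, 0.143, 0.337, 0.143, 0.143, 0.373, 0.432 and 0.432 with an estimated correlation. The list of complement and coagulation genes without TCM peri-tumor 3 or TCM tumor 1 (adjusted p 0.0689 to 0.10) lost its camera call. In NRF2 genes (-0.21, 0.28 and down), IGF axis genes (0.32, 0.26 and down), endothelial genes (-0.04, 0.04 and up), stellate genes (-0.31, 0.18 and down) and lymphatic genes (0.43, 0.23 and down), not called, the median, mean and camera direction differed in sign.

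Tumor effects of the 2 treatments, which share no library, had a Pearson correlation of 0.836 and a Spearman correlation of 0.736 across 14865 genes, which are not independent replicates. Of the 3743 genes called in both, 98.6% moved the same way, 1957 up in both against 566 for independent lists and 1735 down in both against 492.

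**Figure D2:**
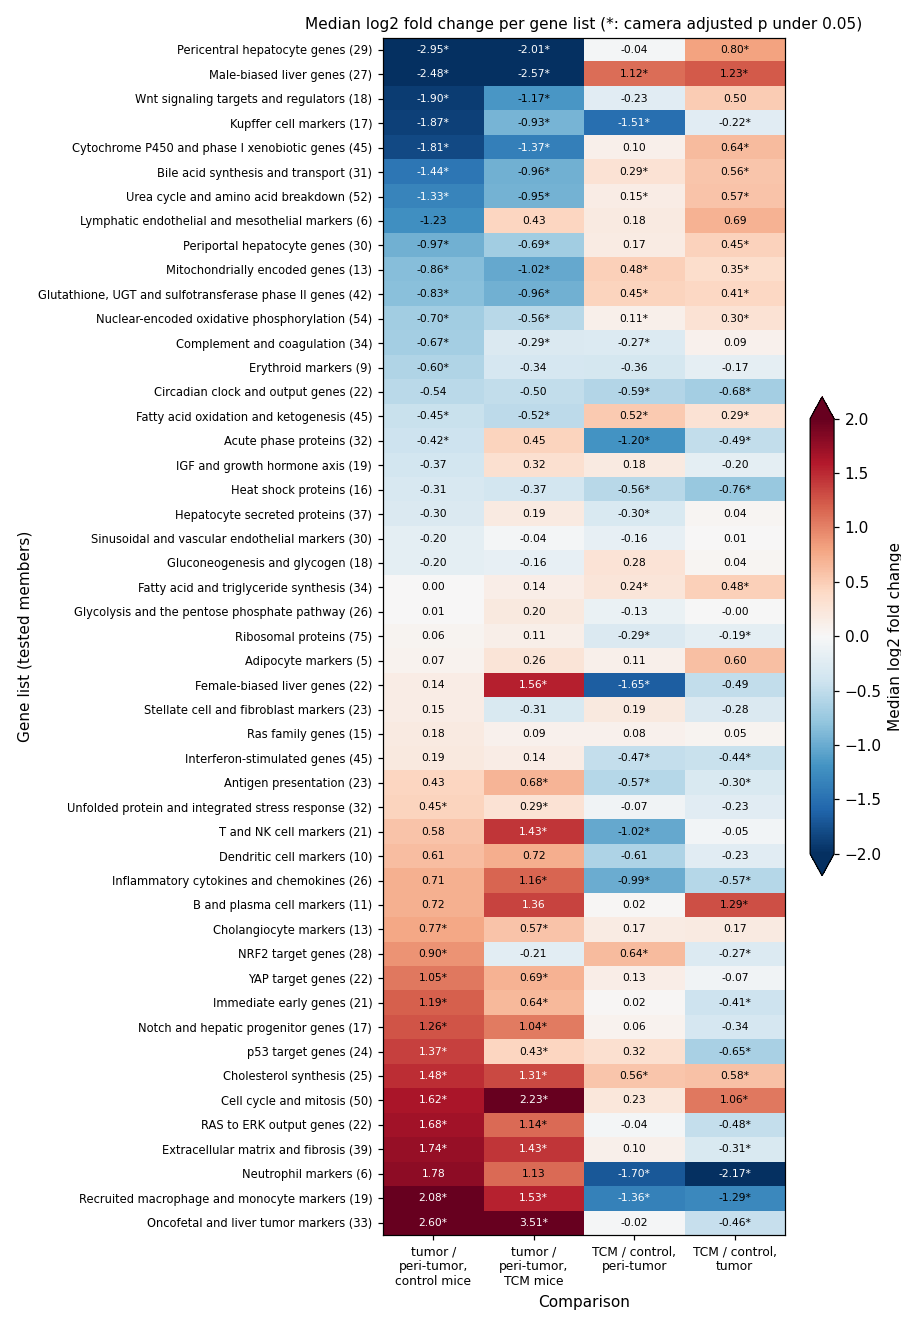
Median log2 fold change of the tested members of 49 gene lists (rows) in the 4 pairwise comparisons (columns), with colors capped at -2 and 2 and an asterisk where the limma camera adjusted p is under 0.05 with the preset correlation. Pericentral genes (median -2.95 in control and -2.01 in TCM mice, limma camera adjusted p = 0.152 and 0.185 with an estimated correlation) are lower in tumors, and acute phase proteins (-1.20, 0.0152) are lower in TCM peri-tumor tissue.

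In peri-tumor liver, TCM mice had higher levels of the drug-metabolizing cytochromes Cyp2b10 and Cyp3a11 and far lower levels of Saa1, Lcn2 and Mt1, than control mice. Cyp2b10 rose from 0.439 ± 0.341 to 10.7 ± 2.28 CPM (24.1-fold, log2 4.59 ± 0.54) and Cyp3a11 from 1221 ± 330 to 5426 ± 1470 (log2 2.15 ± 0.29). The serum amyloid Saa1 fell from 1778 ± 2800 to 15.5 ± 5.13 CPM (log2 -6.84 ± 1.26), where 1 control library, that of mouse 4, stood at 5984 CPM. Lcn2 fell from 348 ± 280 to 7.499 ± 3.68 CPM (log2 -5.54), and Mt1 from 373 ± 168 to 11.6 ± 4.26 (log2 -5.01 ± 0.47). Adjusted p for these 5 genes ran from 8.15e-05 to 0.00348 (edgeR quasi-likelihood test, Benjamini-Hochberg). In all, 2091 genes changed (14.1%), 998 up and 1093 down, 710 of them by at least 2-fold (201 up and 509 down). The count was 1300, 1101, 1269 and 3228 without control peri-tumor 1, 2, 3 and 4, 1217 and 1226 without TCM peri-tumor 1 and 3, and 3434 without control mouse 4. Without control peri-tumor 4 the fold moved over 1.5 times for Saa1 (-4.60) and Lcn2 (-4.80).

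The other large rises were in Npas2 (4.13), Cyp2c55 (3.84), Egr1 (3.82), Cyp4a12a (3.56), Cyp4a12b (3.02), the keratin Krt23 (3.44), the bile acid hydroxylase Cyp8b1 (3.03), Olig1 (2.56) and Slc25a30 (2.51) on the log2 scale. Eif3j2, with 0 counts in the 4 TCM libraries, was at least 578-fold lower, but 91.8% of its 50-base words occur in other genes and its value is uncertain. Saa2 (-8.12), the transporter Slc22a26 (-7.15), Prtn3 (-5.75), Mt2 (-5.46) and Cyp2c69 (-5.43) fell as well, the last also uncertain through shared sequence, as are Cyp4a12a and Cyp4a12b, with 48.9% and 49.4% shared, and Saa1 and Saa2, with 31.7% and 31.8%. Adjusted p of these 15 genes ran from 1.91e-05 to 0.0419 (edgeR quasi-likelihood test, Benjamini-Hochberg). Cyp7a1 fell (-2.17) and Ddx3y (0.64) rose, with adjusted p = 0.0257 and 0.00706 (edgeR quasi-likelihood test, Benjamini-Hochberg). Afp (0.51), Gpc3 (-0.81), Mki67 (0.10), Glul (-0.32), Cyp1a2 (0.06), Alb (0.42), H19 (-0.22), Igf2 (2.65), Dusp6 (-0.03) and Nras (-0.37) were not called. Without TCM peri-tumor 1 the fold moved over 1.5 times for Npas2 (2.71) and Slc25a30 (1.66), without control peri-tumor 4 for Cyp2c55 (4.45), Egr1 (5.05), Cyp4a12a (4.89), Cyp4a12b (3.81) and Saa2 (-4.85), without control peri-tumor 2 for Slc22a26 (-4.98) and Cyp2c69 (-4.74). Eif3j2 without any 1 library but control peri-tumor 4 (adjusted p 0.0576 to 0.0705), Npas2 without control peri-tumor 1 or 2 or TCM peri-tumor 1 (adjusted p 0.0504 to 0.0696) and Cyp4a12a without any 1 library but control peri-tumor 4 (adjusted p 0.0632 to 0.099) were no longer called (edgeR). Cyp4a12b without control peri-tumor 1 or 3 or TCM peri-tumor 1 or 3 (adjusted p 0.0516 to 0.0709) and Cyp7a1 without control peri-tumor 1 or 2 or TCM peri-tumor 1, 3 or 4 (adjusted p 0.0532 to 0.10) were no longer called (edgeR).

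Limma camera (Benjamini-Hochberg) called 24 of 49 gene lists in TCM peri-tumor tissue, 10 up and 14 down, with a preset correlation of 0.01. With the correlation estimated per list 1 of these 24 stayed called, the acute phase proteins, and fry did not call antigen presentation, heat shock, male-biased, mitochondrially encoded, oxidative phosphorylation, T and NK cell and urea cycle genes (adjusted p 0.0578 to 0.277). Counts over the list alone are in parentheses, and the rest was not called. Of 32 acute phase proteins, 0 rose and 22 fell (1 and 26), with Lcn2 at -5.54, Orm3 at -3.87 and Mt2 at -5.46. Of 37 hepatocyte secreted proteins, 0 rose and 7 fell (0 and 8), with Itih3 at -1.61 and Hpx at -1.37. Of 34 complement and coagulation genes, 0 rose and 9 fell (0 and 11), with C3 at -1.12 and Pros1 at -0.84. Of 45 interferon-stimulated genes, 0 rose and 12 fell (0 and 13), with Oas3 at -2.61 and Zbp1 at -1.74. Of 23 antigen presentation genes, 0 rose and 4 fell (0 and 10), with Psmb10 at -1.06 and H2-DMb1 (uncertain) at -1.47. Of 26 cytokine and chemokine genes, 0 rose and 10 fell (0 and 12), with Icam1 at -1.47 and Cxcl1 at -1.53. Of 17 Kupffer cell markers, 0 rose and 13 fell (0 and 15), with C1qb at -1.58 and Cd207 at -2.02. Of 19 recruited macrophage markers, 0 rose and 4 fell (0 and 5), with Fcgr1 at -1.84 and Lgals3 at -1.99. Of 6 neutrophil markers, 0 rose and 1 fell (0 and 1), with S100a8 at -1.86 and S100a9 at -1.53, neither called, and TCM peri-tumor 3 apart in the list mean. Of 21 T and NK cell markers, 0 rose and 1 fell (0 and 1), with Klrk1 at -1.36 and Lck at -1.42, neither called. In defense and secretion lists, camera gave adjusted p = 0.0152, 0.475, 0.40, 0.475, 0.475, 0.40, 0.458, 0.475, 0.475 and 0.677 with an estimated correlation. The list of T and NK cell markers without control peri-tumor 3 (adjusted p 0.0723) lost its camera call. Of 75 ribosomal protein genes, 0 rose and 13 fell (0 and 19), with Rpl41 (uncertain) at -1.14 and Rpl11 (uncertain) at -0.97. Of 16 heat shock proteins, 0 rose and 2 fell (0 and 7), with Hspb1 (uncertain) at -0.98 and Dnaja1 at -0.55, neither called. Of 22 circadian genes, 3 rose and 4 fell (4 and 10), with Noct (uncertain) at -1.81 and Per2 at -2.07. Of 22 female-biased liver genes, 0 rose and 9 fell (2 and 11), with Cyp2c40 (uncertain) at -3.38 and Trim24 at -1.54. For ribosomal to female-biased lists, camera gave adjusted p = 0.475, 0.475, 0.475 and 0.475 with an estimated correlation. The list of circadian genes without control peri-tumor 4 or TCM peri-tumor 1 (adjusted p 0.0626 to 0.0939) lost its camera call. The median of the female-biased list was log2 -1.65, or -1.28 with 3 members that had 0 counts in a group set at their bound. Without control peri-tumor 4 the fold moved over 1.5 times for Lcn2 (-4.80).

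Lipid and detoxification lists were called up in TCM peri-tumor tissue, with counts adjusted over the list alone in parentheses. Of 45 fatty acid oxidation genes, 24 rose and 2 fell (31 and 2), with Etfdh at 0.98, Vnn1 at 1.96 and Acadl at 0.69, and control peri-tumor 4 apart in the list mean. Of 34 fatty acid and triglyceride synthesis genes, 10 rose and 4 fell (11 and 4), with Elovl5 at 2.15 and Me1 (uncertain) at 2.21. Of 25 cholesterol synthesis genes, 9 rose and 0 fell (10 and 0), with Tm7sf2 at 0.79 and Msmo1 at 1.18. Of 31 bile acid genes, 8 rose and 2 fell (10 and 2), with Cyp8b1 at 3.03 and Hsd17b4 at 0.59, and TCM peri-tumor 3 apart in the list mean. For lipid and bile acid lists, camera gave adjusted p = 0.0806, 0.475, 0.475 and 0.475 with an estimated correlation. The list of fatty acid and triglyceride synthesis genes without control peri-tumor 4 (adjusted p 0.151) lost its camera call. Of 52 urea cycle and amino acid breakdown genes, 10 rose and 1 fell (11 and 1), with Gldc at 0.98 and Asl at -1.31. Of 54 nuclear-encoded oxidative phosphorylation genes, 7 rose and 1 fell (9 and 1), with Ndufs1 at 0.49 and Cox7a2 at 0.57. Of 13 mitochondrially encoded genes, 1 rose and 0 fell (5 and 0), with mt-Nd1 at 0.48 and mt-Nd5 at 0.496, neither called. Of 42 phase II conjugation genes, 9 rose and 0 fell (12 and 0), with Gstm6 at 1.33 and Gstm4 at 1.57. Of 28 NRF2 target genes, 7 rose and 1 fell (10 and 1), with Aox1 at 1.73 and Gclc at 1.503. Of 27 male-biased liver genes, 4 rose and 0 fell (7 and 0), with Ugt2b38 (uncertain) at 1.31. For other metabolic lists, camera gave adjusted p = 0.597, 0.677, 0.475, 0.458, 0.475 and 0.475 with an estimated correlation. The list of urea cycle and amino acid breakdown genes without control peri-tumor 4 (adjusted p 0.209) and the list of nuclear-encoded oxidative phosphorylation genes without control peri-tumor 4 (adjusted p 0.227) lost their camera call. In oncofetal genes (-0.02, -0.06 and up), cytochrome P450 genes (0.10, -0.25 and up), matrix genes (0.10, -0.01 and up), IGF axis genes (0.18, 0.00115 and down) and lymphatic genes (0.18, -0.01 and down), not called, the median, mean and camera direction differed in sign.

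**Figure D3:**
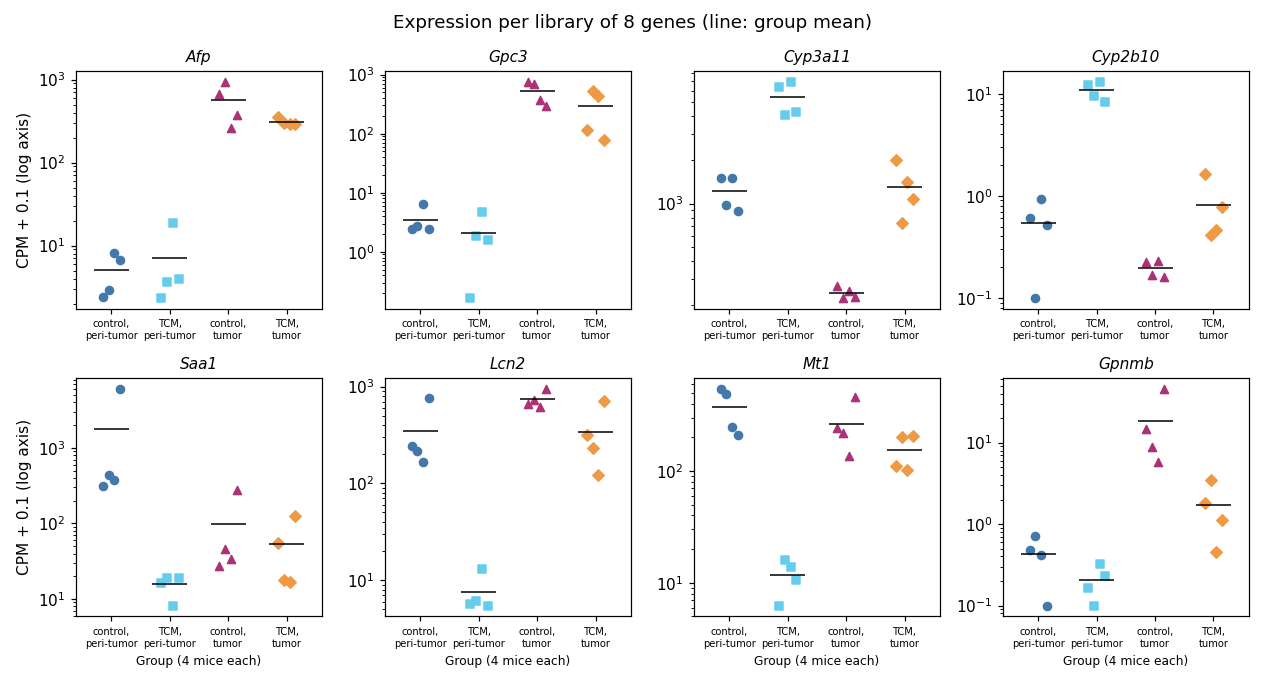
CPM plus 0.1, on a log axis, of Afp, Gpc3, Cyp3a11, Cyp2b10, Saa1, Lcn2, Mt1 and Gpnmb in each of the 16 libraries (points) of the 4 groups, with a line at each group mean. Cyp2b10 lies at 8.12 to 13.1 CPM in the 4 TCM peri-tumor libraries and at 0 to 0.827 in the 4 control ones, and Saa1 of control mouse 4 stands at 5984 CPM.

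In tumors, TCM mice had higher levels of Cyp3a11 and Cyp8b1, which hepatocytes use to metabolize drugs and bile acids, and lower levels of Gpnmb and Igfbp3 than control mice. Cyp3a11 rose from 242 ± 21.4 to 1304 ± 539 CPM (5.39-fold, log2 2.43 ± 0.29) and Cyp8b1 from 2.19 ± 0.635 to 19.6 ± 12.5 (log2 3.16 ± 0.49). Gpnmb, made by lipid-laden macrophages, fell from 18.6 ± 18.1 to 1.62 ± 1.31 CPM (log2 -3.49 ± 0.68), and the growth factor binding protein Igfbp3 from 379 ± 182 to 87.9 ± 49.4 (log2 -2.11 ± 0.37). Adjusted p for these 4 genes ran from 6.11e-04 to 0.00919 (edgeR quasi-likelihood test, Benjamini-Hochberg). The tumor markers Afp (-0.86, adjusted p = 0.343) and Gpc3 (-0.87, adjusted p = 0.423) and the proliferation gene Mki67 (1.14, adjusted p = 0.0773) were not called by the edgeR quasi-likelihood test, Benjamini-Hochberg. In all, 1082 genes changed (7.28%), 677 up and 405 down, 405 of them by at least 2-fold. The count was 665, 404 and 583 without control tumor 1, 2 and 3, 663 and 407 without TCM tumor 1 and 3, and 1877 without control mouse 4. Without control tumor 4 the fold moved over 1.5 times for Gpnmb (-2.55), without TCM tumor 2 for Gpnmb (-4.12).

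The other large rises in TCM tumors were in Hamp2 (4.13), Cyp2c55 (3.12), Car3 (3.06), the coenzyme Q gene Coq8a (2.52), Plekhd1 (2.35), Spon2 (2.22), Bhmt (2.15) and its pseudogene Bhmt-ps1 (2.17, uncertain with 69.4% shared sequence). Cyp2b10 rose as well (2.82). Zc3h11a (-2.58, uncertain with 97.5% shared), Cxcl17 (-2.58), Oas3 (-2.56), Gprc5a (-2.31), Lilr4b (-2.24), Nrg4 (-2.24), Tnc (-2.21) and Kdelr3 (-2.09) completed the largest falls. Adjusted p of these 17 genes ran from 9.67e-04 to 0.0489 (edgeR quasi-likelihood test, Benjamini-Hochberg). Glul (1.05), Cyp1a2 (1.25), Cyp7a1 (0.51), H19 (0.36), Igf2 (-1.92), Dusp6 (-0.49), Nras (-0.27), Alb (0.09) and Ddx3y (0.10) were not called. Without TCM tumor 3 the fold moved over 1.5 times for Hamp2 (2.94), without control tumor 4 for Cyp2c55 (4.74), Car3 (4.16), Plekhd1 (2.94), Lilr4b (-1.36) and Tnc (-0.83), without TCM tumor 1 for Cyp2b10 (2.17), without TCM tumor 4 for Kdelr3 (-2.79). Hamp2 without any 1 library but TCM tumor 4 (adjusted p 0.0563 to 0.175), Plekhd1 without control tumor 1, 2 or 3 or TCM tumor 1 or 3 (adjusted p 0.0534 to 0.11) and Spon2 without control tumor 1, 2 or 3 or TCM tumor 3 (adjusted p 0.0566 to 0.0683) were no longer called (edgeR). Cyp2b10 without any 1 library but TCM tumor 2 and 4 (adjusted p 0.0542 to 0.116), Zc3h11a without any 1 library but control tumor 4 and TCM tumor 2 (adjusted p 0.062 to 0.114) and Lilr4b without TCM tumor 3 (adjusted p 0.059) were no longer called (edgeR). Tnc without any 1 library but control tumor 1 and 3 (adjusted p 0.0524 to 0.229) and Kdelr3 without any 1 library but TCM tumor 4 (adjusted p 0.052 to 0.132) were no longer called (edgeR).

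Limma camera (Benjamini-Hochberg) called 30 of 49 gene lists in TCM tumors against control tumors, 14 up and 16 down, with a preset correlation of 0.01. With the correlation estimated per list 0 of these 30 stayed called, fry called 9 (RAS to ERK output, periportal, urea cycle, bile acid, fatty acid oxidation, oxidative phosphorylation, cytochrome P450, interferon and recruited macrophage genes), and another split of the libraries also gave 30. Counts over the list alone are in parentheses, and the rest was not called. Of 50 cell cycle genes, 13 rose and 0 fell (27 and 0), with Rrm2 at 0.90. Of 29 pericentral hepatocyte genes, 7 rose and 0 fell (13 and 0), with Notum at 1.57. Of 30 periportal hepatocyte genes, 7 rose and 0 fell (14 and 1), with Gldc at 0.83 and Hal at 0.94. Of 52 urea cycle and amino acid breakdown genes, 28 rose and 0 fell (34 and 0), with Haao at 1.09, Aldh4a1 (uncertain) at 0.86 and Dmgdh at 1.23. Of 31 bile acid genes, 9 rose and 1 fell (15 and 1), with Nr0b2 at 1.45 and Cyp8b1 at 3.16. From cell cycle to bile acid lists, camera gave adjusted p = 0.377, 0.424, 0.236, 0.135 and 0.135 with an estimated correlation. Of 45 fatty acid oxidation genes, 5 rose and 0 fell (8 and 0), with Etfdh at 0.85. Of 34 fatty acid and triglyceride synthesis genes, 5 rose and 0 fell (8 and 0), with Acss2 at 1.71, Elovl5 at 1.31 and Scd1 at 1.81. Of 25 cholesterol synthesis genes, 4 rose and 0 fell (6 and 0), with Tm7sf2 at 0.93 and Acat2 (uncertain) at 1.22. Of 54 nuclear-encoded oxidative phosphorylation genes, 12 rose and 0 fell (21 and 0), with Sdha at 0.63. Of 13 mitochondrially encoded genes, 1 rose and 0 fell (2 and 0), with mt-Atp8 at 0.59 and mt-Co2 (uncertain) at 0.496, neither called. Of 45 cytochrome P450 and phase I genes, 13 rose and 1 fell (20 and 2), with Cyp3a25 (uncertain) at 1.63, Ces2a at 1.66 and Cyp2j5 at 1.48. Of 42 phase II conjugation genes, 7 rose and 0 fell (13 and 0). Of 27 male-biased liver genes, 0 rose and 0 fell (0 and 0), with Mup3 at 1.23 and Elovl3 at 3.72, neither called. Of 11 B and plasma cell markers, 0 rose and 0 fell (6 and 0), with Ighm at 1.29 and Jchain at 1.67, neither called. From fatty acid oxidation to B cells, camera gave adjusted p = 0.377, 0.377, 0.436, 0.377, 0.536, 0.377, 0.377, 0.424 and 0.377 with an estimated correlation. The list of B and plasma cell markers without TCM tumor 1 or 2 (adjusted p 0.0539 to 0.181), with the filter of 1 CPM in 4 libraries (0.198) and with only the groups compared (0.165) lost its camera call.

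Lists of signaling, stress and immune genes were called down in TCM tumors, with counts adjusted over the list alone in parentheses. Of 22 RAS to ERK output genes, 0 rose and 2 fell (0 and 5), with Phlda1 at -0.72 and Spred1 at -0.42, neither called. Of 33 oncofetal and liver tumor markers, 0 rose and 4 fell (0 and 6). Of 28 NRF2 target genes, 1 rose and 1 fell (2 and 5), with Cyp2a5 (uncertain) at -1.37 and Cbr3 at -2.15, neither called. Of 24 p53 target genes, 1 rose and 4 fell (1 and 10). Of 21 immediate early genes, 1 rose and 1 fell (1 and 5), with Klf4 at -1.34 and Maff at -1.04, neither called. Of 16 heat shock proteins, 0 rose and 2 fell (0 and 8), with Dnajb1 at -1.11 and Hspb1 (uncertain) at -0.98 (not called). Of 22 circadian genes, 0 rose and 2 fell (1 and 2), with Noct (uncertain) at -1.55. Of 75 ribosomal protein genes, 1 rose and 3 fell (1 and 3), with Rpl23a (uncertain) at -0.79 and Rpl11 (uncertain) at 1.07. For signaling and stress lists, camera gave adjusted p = 0.236, 0.377, 0.574, 0.377, 0.377, 0.377, 0.377 and 0.536 with an estimated correlation. The list of NRF2 target genes without control tumor 1 or 3 or TCM tumor 3 (adjusted p 0.0533 to 0.368), with only the groups compared (0.0907) and the list of circadian genes without TCM tumor 1 (adjusted p 0.0503) lost their camera call. Of 32 acute phase proteins, 2 rose and 4 fell (3 and 5), with Lbp at -0.79. Of 45 interferon-stimulated genes, 0 rose and 9 fell (0 and 14), with Oas3 at -2.56. Of 23 antigen presentation genes, 0 rose and 0 fell (0 and 0), with H2-T22 (uncertain) at -0.496 and H2-D1 at -0.39, neither called. Of 26 cytokine and chemokine genes, 0 rose and 2 fell (0 and 7), with Tnfaip3 at -0.73 and Icam1 at -0.65, neither called. Of 39 extracellular matrix genes, 0 rose and 1 fell (0 and 1), with Dcn at -0.58 and Timp1 at -1.77, neither called. Of 17 Kupffer cell markers, 0 rose and 2 fell (0 and 3), with Cd207 at -1.16 and Cd5l at -0.90, neither called. Of 19 recruited macrophage markers, 0 rose and 8 fell (0 and 15), with Fcgr1 at -1.55 and Trem2 at -2.36, and control tumor 4 apart in the list mean. Of 6 neutrophil markers, 0 rose and 1 fell (0 and 4), with S100a9 at -2.74 and Mmp9 at -2.68, neither called. For immune and matrix lists, camera gave adjusted p = 0.377, 0.377, 0.536, 0.377, 0.584, 0.563, 0.236 and 0.402 with an estimated correlation. The list of extracellular matrix genes without control tumor 4 or TCM tumor 1 (adjusted p 0.0503 to 0.563), the list of Kupffer cell markers without TCM tumor 4 (adjusted p 0.637) and the list of neutrophil markers without control tumor 4 (adjusted p 0.152), with only the groups compared (0.0549) lost their camera call. In endothelial genes (0.01, 0.02 and down), erythroid genes (-0.17, -0.01 and up), not called, the median, mean and camera direction differed in sign. Without control tumor 4 the fold moved over 1.5 times for Trem2 (-1.52).

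Treatment effects in the 2 tissues, which share no library but come from the same 8 mice, had a Pearson correlation of 0.385 and a Spearman correlation of 0.347 across 14865 genes. Of the 379 genes called in both tissues, Cyp3a11, Cyp8b1 and Oas3 among them, 91.3% moved the same way, 191 up in both against 45.5 for independent lists and 155 down in both against 29.8. Of 803 genes called both for control tumors against peri-tumor tissue and for TCM against control tumors, 750 moved in opposite directions, 523 lower in tumors and higher with TCM against 143 for independent lists and 227 the other way against 89.1. These last comparisons share the 4 control tumor libraries.

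The tumor effect differed between TCM and control mice for the metallothioneins Mt1 and Mt2 and for Lcn2, all lower with TCM in peri-tumor tissue. The difference was log2 4.24 for Mt1, 4.49 for Mt2 and 4.43 for Lcn2, where positive values mean a higher tumor effect in TCM mice. Mt1 stood at 373 ± 168 and 265 ± 140 CPM in control and 11.6 ± 4.26 and 155 ± 56.4 in TCM peri-tumor and tumor tissue. The protease Prtn3 (5.29 ± 0.57) had the largest difference of the 10 genes with the lowest p, at 27.9 ± 8.2 and 8.47 ± 2.19 CPM in control and 0.508 ± 0.0556 and 6.17 ± 4.34 in TCM mice. Adjusted p of these 4 genes ran from 3.54e-04 to 0.010 (edgeR quasi-likelihood test, Benjamini-Hochberg). In all, 165 genes were called (1.11%), 60 of them with a negative difference, and 107 with the mouse as a block, 75 of them shared. The count was 84, 79, 93 and 665 without control peri-tumor 1 to 4, 74, 71, 78 and 269 without control tumor 1 to 4, 58 to 107 without any 1 of TCM peri-tumor 1, 2 and 3 and TCM tumor 1 and 3 (58 without TCM tumor 3 and 107 without TCM peri-tumor 2), 270 without TCM tumor 4, and 714 without control mouse 4. Without control tumor 4 the fold moved over 1.5 times for Mt2 (5.38), without control peri-tumor 4 for Lcn2 (3.69), without TCM tumor 4 for Lcn2 (3.84).

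The other 9 of the 10 genes with the lowest p were Gm11539 (4.58), Rpl35a-ps3 (3.35), Gm10736 (3.15), the respiratory subunit Cox7c (2.68), the mitochondrial transfer RNA mt-Tp (2.32), Gm7392 (2.04), Gm3379 (2.01), Gm6204 (-1.81) and Zbed5 (-1.62). Their adjusted p ran from 1.49e-04 to 0.00176 (edgeR quasi-likelihood test, Benjamini-Hochberg). All but mt-Tp and Zbed5 are uncertain, with 41.3%, 100%, 100%, 27.9%, 53.7%, 90.4% and 31.4% of their 50-base words in other genes for Gm11539, Rpl35a-ps3, Gm10736, Cox7c, Gm7392, Gm3379 and Gm6204. Cyp2c69 (4.47, with 54.8% shared), Egr1 (-3.78) and Igfbp3 (-3.06) were called too. Afp (-1.37), Gpc3 (-0.06), Mki67 (1.04), Glul (1.37), Cyp7a1 (2.68), Cyp1a2 (1.19), Cyp2b10 (-1.77), Cyp3a11 (0.28), Nras (0.09), Dusp6 (-0.46), H19 (0.58), Igf2 (-4.57), Alb (-0.33) and Ddx3y (-0.53) were not called. Without control peri-tumor 2 the fold moved over 1.5 times for Cyp2c69 (3.81), without control peri-tumor 4 for Egr1 (-5.02). Cyp2c69 without any 1 library but control peri-tumor 3 and 4 and control tumor 4 (adjusted p 0.0527 to 0.0866) and Egr1 without any 1 library but control peri-tumor 4, control tumor 4, TCM peri-tumor 2 and 4 and TCM tumor 2 and 4 (adjusted p 0.0539 to 0.070) were no longer called (edgeR).

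Limma camera (Benjamini-Hochberg) called 20 of 49 gene lists for the difference of the tumor effect, 12 up and 8 down, with a preset correlation of 0.01. With the correlation estimated per list 0 of these 20 stayed called, fry called 2 (acute phase and complement genes), and another split of the mice gave 21. Counts over the list alone are in parentheses, and the rest was not called. Of 32 acute phase proteins, 4 were positive and 0 negative (18 and 0), with Mt1 at 4.24 and Saa4 at 1.29. Of 34 complement and coagulation genes, 1 was positive and 0 negative (9 and 0), with F7 at 1.17 and C4b (uncertain) at 0.75 (not called). Of 37 hepatocyte secreted proteins, 1 was positive and 0 negative (8 and 0), with Vtn at 0.85 and Hpx at 1.09 (not called). Of 52 urea cycle and amino acid breakdown genes, 5 were positive and 0 negative (14 and 0), with Haao at 1.19 and Bhmt2 at 0.88. Of 29 pericentral hepatocyte genes, 1 was positive and 0 negative (11 and 0), with Cyp27a1 at 0.82 (not called). Of 30 periportal hepatocyte genes, 0 were positive and 0 negative (4 and 0), with Ass1 (uncertain) at 0.97 and Hpd at 1.97, neither called. Of 54 nuclear-encoded oxidative phosphorylation genes, 1 was positive and 0 negative (1 and 0), with Ndufb7 at 0.46 (not called). Of 45 cytochrome P450 and phase I genes, 1 was positive and 0 negative (5 and 1), with Nr1i2 at 0.69 (not called). Of 50 cell cycle genes, 1 was positive and 0 negative (1 and 0), with Rrm2 at 1.79. Of 18 Wnt targets and regulators, 1 was positive and 0 negative (1 and 0), with Glul at 1.37 and Axin2 at 1.85, neither called. Of 22 female-biased liver genes, 1 was positive and 0 negative (2 and 0), with Fmo2 at 2.89 (not called). Of 17 Kupffer cell markers, 0 were positive and 0 negative (6 and 0), with Fcna at 1.78 and Clec4f at 1.56, neither called. For lists with a positive median, camera gave adjusted p = 0.0846, 0.271, 0.563, 0.474, 0.679, 0.563, 0.718, 0.712, 0.712, 0.612, 0.718 and 0.679 with an estimated correlation. The list of periportal hepatocyte genes without control peri-tumor 1 or 3, control tumor 3 or 4, TCM peri-tumor 1 or 4 or TCM tumor 2 or 3 (adjusted p 0.051 to 0.0979), the list of nuclear-encoded oxidative phosphorylation genes without control peri-tumor 1 (adjusted p 0.0765) and the list of cytochrome P450 and phase I genes without control peri-tumor 1 or 2 or TCM tumor 1 or 2 (adjusted p 0.0652 to 0.0975) lost their camera call. The list of Wnt targets and regulators without control peri-tumor 1, 2 or 4 (adjusted p 0.0513 to 0.067) and the list of female-biased liver genes without any 1 library but control peri-tumor 3 and 4, control tumor 1 and 2, TCM peri-tumor 3 and TCM tumor 1 (adjusted p 0.0563 to 0.30), with the filter of 1 CPM in 4 libraries (0.0522) lost their camera call. Of 22 RAS to ERK output genes, 0 were positive and 0 negative (0 and 0), with Dusp4 at -1.25 and Dusp5 at -1.29, neither called. Of 33 oncofetal and liver tumor markers, 1 was positive and 0 negative (1 and 4), with Abcc4 at -1.83 and Lgals1 at -1.21, neither called. Of 45 fatty acid oxidation genes, 0 were positive and 2 negative (0 and 2), with Eci2 at -0.52 (not called). Of 28 NRF2 target genes, 0 were positive and 2 negative (0 and 9), with Aox1 at -1.74. Of 24 p53 target genes, 0 were positive and 1 negative (0 and 7), with Ccng1 at -1.25 (not called). Of 21 immediate early genes, 0 were positive and 1 negative (1 and 1), with Klf6 at -0.62 (not called). Of 39 extracellular matrix genes, 0 were positive and 0 negative (0 and 0), with Col14a1 at -0.69 and Dcn at -0.79, neither called. Of 23 stellate cell markers, 0 were positive and 0 negative (0 and 0), with Pdgfrb at -0.83 and Hgf at -0.59, neither called. For lists with a negative median, camera gave adjusted p = 0.474, 0.679, 0.474, 0.474, 0.474, 0.474, 0.797 and 0.679 with an estimated correlation. The list of oncofetal and liver tumor markers without control peri-tumor 1, TCM peri-tumor 3 or TCM tumor 3 (adjusted p 0.0611 to 0.193), the list of immediate early genes without TCM peri-tumor 4 (adjusted p 0.0977) and the list of extracellular matrix genes without control peri-tumor 1, control tumor 4 or TCM peri-tumor 2 (adjusted p 0.0522 to 0.349) lost their camera call. The list of stellate cell markers without control peri-tumor 1, control tumor 4, TCM peri-tumor 2 or TCM tumor 3 (adjusted p 0.0506 to 0.105) lost its camera call. In gluconeogenesis genes (0.08, -0.04 and up), phase II genes (0.06, -0.13 and down), interferon genes (0.06, 0.05 and down), IGF axis genes (0.17, -0.20 and down), male-biased genes (0.34, 0.20 and down) and neutrophil genes (-1.04, 0.09 and up), not called, the median, mean and camera direction differed in sign. F7 without control peri-tumor 1, control tumor 2, TCM peri-tumor 1 or 3 or TCM tumor 3 (adjusted p 0.0531 to 0.062) was no longer called (edgeR).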

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

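Among the tests below, those of immune cells and of time of day were chosen only after the result was seen. The other predictions were written before their test.

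Of 165 genes called for the difference of the tumor effect, 26.7% were pseudogenes, against 7.81% of genes tested. Reads shared between near-identical copies fit part of the calls. With 50% or more words shared, 33 of 1203 genes (2.74%) were called, against 96 of 11861 (0.809%) under 5%. The ratio was 3.39, and 0.675 in control tumors against peri-tumor tissue. Two-sided Fisher exact p = 4.06e-08 takes such copies as independent and may be too low. Gene length stays open. With under 5% shared, 1.18% of the 2966 shortest (up to 2241 bases) and 0.686% of 8895 others were called (ratio 1.72). In all but Prtn3 and mt-Tp of the 10 lowest-p genes, control peri-tumor and TCM tumor means lay on 1 side of the others. Gm10736 had 6.3 and 6.6 against 2.2 and 2.1 CPM. Batches, not named in the labels, were not tested, and a decoction effect, not tested apart from these, stays open.

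Acute phase transcripts were lower in TCM than in control peri-tumor tissue, and control mouse 4, whose Saa1 stood apart, is not the cause of the list's call, since without both of its libraries the median was -1.18, 24 of 32 members fell and limma camera gave adjusted p = 2.32e-13. Fewer immune cells in the TCM peri-tumor pieces cannot be excluded. The Kupffer, recruited macrophage, neutrophil and T and NK lists were called down (medians -1.51, -1.36, -1.70 and -1.02). With an estimated correlation limma camera gave adjusted p = 0.458, 0.475, 0.475 and 0.677 for them. The T and NK list was not called with fry (adjusted p 0.277) or without control peri-tumor 3 (limma camera adjusted p 0.0723). B and plasma cell (median 0.0214) and dendritic markers (median -0.61) were not called. Time of day or handling cannot be excluded, since the circadian list had a median of -0.59 and was called, though not without control peri-tumor 4 (limma camera adjusted p 0.0626) or TCM peri-tumor 1 (0.0939), and with adjusted p = 0.475 with an estimated correlation. Arntl (2.50), Clock (1.19), Npas2 (4.13), Per2 (-2.07), Noct (-1.81), Usp2 (-2.38) and Bhlhe40 (-0.90) were called, and Dbp (-0.30), Per1 (-1.30) and Nr1d1 (1.35) were not. A lower inflammatory response under the decoction stays open and was not tested apart from these.

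Of the 803 genes called in both comparisons with control tumors, 750 moved back towards the peri-tumor level with TCM. Noise of the shared control tumor libraries is excluded as the whole cause. The slope of the treatment effect on the tumor effect was -0.226. It was -0.216 to -0.157 over 6 splits of control tumors that share none, and -0.0414 to -0.0282 in 20 simulated draws without treatment effect. Peri-tumor tissue in TCM tumor pieces stays open for genes low in tumors. The share needed by 66 such genes had lower and upper deciles of 5.02% and 19.4% and a median of 9.47%. The ratio of lower decile to median was 0.53, and 0.523 without 16 Mup genes, which share sequence. Shares ran from -18.9% (Prlr) to 45.2% (Afmid). Even 45.2% is too small for falls such as those of Igfbp3 (379 to 87.9 CPM) and Cxcl17 (49.5 to 8.25 CPM). Such tissue would not raise cell cycle or lower Kupffer lists, called so in TCM tumors but not with an estimated correlation. A treatment effect on tumor cells could give similar shares, was not tested apart and stays open.

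Relabelled splits of the libraries were tested as well. For treatment in peri-tumor tissue only the real 1 of 35 splits reached 2091 genes (highest other 54) or 24 lists (highest other 22, median 14.5). In tumors only it reached 1082 genes (highest other 135). Chance is excluded there, for the lists only as called here. Lists were 20 without control peri-tumor 4, 21 without control mouse 4, 19 with fry and 1 with an estimated correlation. For lists in tumors 2 splits reached 30 (highest other 30, median 19). For lists of the difference 3 reached 20 (highest other 21, median 10.5). Chance is not excluded for either. Only the real split reached the 165 genes of the difference (highest other 12), with the same limits as above. For tumor against peri-tumor tissue the 8 splits that part all 4 mice are too few for a share under 0.05. In control and TCM mice 1 reached 6415 and 4897 genes (highest other 0 and 1). In both 3 reached the 28 and 29 lists (highest other 34 and 32). Splits that part fewer mice gave at most 7 genes and 36 lists, and medians over all other splits were 19 and 15.5 lists. A single list call thus carries little weight.

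The tumor effect differed between TCM and control mice, tested by the interaction term of the edgeR quasi-likelihood fit (Benjamini-Hochberg), for Prtn3 (log2 5.29), Gm11539 (4.58), Mt2 (4.49), Cyp2c69 (4.47), Lcn2 (4.43), Mt1 (4.24), Rpl35a-ps3 (3.35), Gm10736 (3.15), Cox7c (2.68), Hectd2os (2.33), mt-Tp (2.32), Gm7392 (2.04), Gm3379 (2.01), Zbed5 (-1.62), Gm6204 (-1.81), Igfbp3 (-3.06) and Egr1 (-3.78). Limma camera with the preset correlation called 20 lists, of which 0 stayed called with an estimated correlation (adjusted p = 0.0846 to 0.797) and 2, acute phase and complement genes, with fry, with median differences of 1.06 for female-biased, 0.94 for pericentral and 0.94 for Kupffer, 0.87 for acute phase, 0.69 for cytochrome P450, 0.63 for Wnt, 0.39 for cell cycle, 0.38 for complement and 0.38 for urea cycle, 0.36 for hepatocyte secreted, 0.33 for periportal and 0.18 for oxidative phosphorylation genes. The medians were -0.23 for fatty acid oxidation, -0.38 for RAS to ERK output, -0.40 for stellate and -0.40 for oncofetal, -0.43 for matrix, -0.88 for immediate early, -0.98 for p53 and -1.14 for NRF2 genes.

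Of 568 groups of 4 values, 40 held a library that stood apart from the other 3 by Dixon's test, where chance gives 28 at about 1 in 20. In control peri-tumor tissue these were library 1 for the mean of the Wnt list (log2 3.25 CPM), library 2 for the Alb share of counts (5.24%, 49890 CPM), Bhmt-ps1 (159 CPM), Cdhr2 (0.121), Olig1 (0.726) and Tmem150c (0.0605), library 3 for the p53 list (log2 3.18), Gm7392 (20.5 CPM), Gpc3 (6.36), Mki67 (4.33), Pla2g2e (0.0636), Rpl35a-ps3 (11.6) and Tnc (0.509), and library 4 for the fatty acid oxidation list (log2 6.08), Csn3 (0.628 CPM), Eif3j2 (22.8), Gm3379 (12.7) and Saa1 (5984). In control tumors library 4 stood apart for genes detected (20533), recruited macrophage markers (log2 4.79) and Moxd1 (23.2 CPM). In TCM peri-tumor tissue these were library 1 for sinusoidal endothelial markers (log2 3.96), library 2 for Csn3 (0.135 CPM), library 3 for the bile acid list (log2 7.43), the neutrophil list (-0.49), Hkdc1 (0.302 CPM), Lcn2 (13) and Pla2g2e (0.227), and library 4 for Arhgap40 (0.064 CPM), Cdkn2a (0.192), Pcdhgc4 (0.064), Spon2 (3.84) and Tmc5 (0.192). In TCM tumors these were library 1 for the YAP list (log2 3.61), Afp (351 CPM) and Mup1 (436), library 3 for Gm3379 (16.2), and library 4 for Cyp1a2 (29.0) and Prtn3 (12.7).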

How the results depend on the processing

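Leaving out control mouse 4 was chosen only after the data were seen, and the other alternatives before. Under RLE factors and a filter of 1 CPM in 4 libraries, and in the 4 pairwise comparisons with only the groups compared, the counts of genes stayed within 1.5 times. DESeq2 called 1805 genes for treatment in tumors and 806 for the difference of the tumor effect, limma-voom 3349 for treatment in peri-tumor tissue, 2193 in tumors and 603 for the difference, and the fit with no low-count filter 687 in tumors and 79 for the difference, where more genes are tested. On simulated data DESeq2 had 19%, 13.2% and 20% false calls for treatment in peri-tumor tissue, in tumors and for the difference. Limma-voom had 6.47%, 5.08% and 6.31%, and edgeR 7.95%, 5.52% and 7.96%. How these rates bear on the real data and why the counts moved was not tested. With the mouse as a block, 107 genes were called for the difference (75 shared), and this block changed no other count by over 1.5 times (6559 and 5044 genes for tumor against peri-tumor in control and in TCM mice, and 30, 31 and 21 lists). With the replicate number as a block, which the design does not pair, 1213 genes were called for treatment in peri-tumor tissue and 476 in tumors, and lists were 24 and 30, without the NRF2 list in tumors (adjusted p 0.0545, limma camera). Number pairs correlated at 0.11, 0.049, 0.085 and 0.0066 in peri-tumor tissue and -0.098, -0.0043, -0.06 and -0.1 in tumors. With the correlation estimated per list, 0, 0, 1, 0 and 0 lists were called for tumor against peri-tumor in control and in TCM mice, for treatment in peri-tumor tissue and in tumors, and for the difference, and fry called 9 in tumors and 2 for the difference. Each library left out in turn gave 1101 to 3228 genes for treatment in peri-tumor tissue, 404 to 1250 in tumors, 58 to 665 for the difference of the tumor effect, 5759 to 6704 for control tumors and 4098 to 4559 for TCM tumors, and 13 to 25 lists for the difference. Without both libraries of control mouse 4, 3434 (1959 shared), 1877 (988 shared) and 714 (161 shared) genes were called for treatment in peri-tumor tissue, in tumors and for the difference. Of the named values in control tumors against peri-tumor tissue, only Csf3r reversed, from log2 1.80 to -0.095 without those libraries. All others kept their direction. In the order of comparisons given for the estimated correlation, 58, 73, 252, 409 and 183 values of a gene under an alternative lost a call and 35, 18, 114, 152 and 204 gained one. Named by the rule, 3 of 33, 3 of 27, 5 of 24, 8 of 21 and 0 of 10 called genes lost their call without some 1 library, and of the list examples 7 of 168, 7 of 160, 33 of 117, 62 of 97 and 17 of 29. Depth limits genes with few counts, for which only floors or wide counting intervals can be given.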

Other observations

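The genes Kctd12 and Klhdc7a, chosen only after their counts were seen, had many counts in some libraries of a group and 0 in others. Kctd12, on the minus strand of chromosome 14 at 102976581 to 102982637 (GRCm38, GENCODE M21), had 448, 913, 675 and 0 counts in the peri-tumor libraries of control mice 1 to 4 and 2621, 2049, 2060 and 995 in their tumors. In TCM mice it had 0, 0, 0 and 267 counts in peri-tumor tissue and 993, 1359, 589 and 0 in tumors. Klhdc7a, on the minus strand of chromosome 4 at 139960220 to 139968026, had 959, 0, 897 and 1304 counts in control peri-tumor tissue and 0 in all 4 control tumors, and 0, 0, 0 and 1002 counts in TCM peri-tumor tissue and 0, 0, 0 and 1004 in TCM tumors. Little of their sequence occurs in other genes, 0.699% for Kctd12 and 2.19% for Klhdc7a.

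The gene Eif3j2, at 43475418 to 43477796 on chromosome 18, had 448, 0, 452 and 0 counts in control tumors and 391, 0, 0 and 317 in TCM tumors, but 91.8% of its words occur in other genes. Gm20716, Gm49388, Hist2h2aa1 and Gm20634 had 0 counts in some libraries of a group and many in others as well, with 88.6%, 97.4%, 89.4% and 77.6% of their sequence shared. No explanation of these counts was tested.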
